A study of Mus musculus with 9 samples.

How the data were processed

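RNA from mouse adult fibroblasts was extracted with a column kit, made into libraries with a TruSeq kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name GRCm38, Trim Galore, cutadapt, STAR, RSEM, limma and edgeR, without versions, roles or order. The annotation release, the strand setting and whether RSEM estimates were rounded are not given in the sources used here. Antisense and overlapping genes therefore cannot be told apart, and genes with near-identical copies are uncertain.

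The authors deposited 2 tables of the whole series. The first holds raw counts, whole numbers per Ensembl gene. The second is named as normalized, but all 159498 of its values equalled the count of the same gene and library in the first. Values were compared as whole numbers, so decimals, if any, were not compared. The second table held the genes whose CPM summed over the 9 libraries exceeded 1. The deposited counts of the first table were used throughout, and the second gave no separate normalization. Gene symbols, coordinates, exonic lengths and GC content came from the GENCODE annotation of GRCm38. Of the IDs, 105 had no symbol there, with 0.0090% of counts. Every column was mapped to a sample by its name.

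Genes were filtered with filterByExpr by group, which kept 14088 genes, with 99.9% of counts in the library where their share was lowest. Counts were scaled by TMM (factors 0.98 to 1.02). All 9 libraries were fitted together with 1 mean per group in edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors of genes were the log2 change divided by the root of the quasi-likelihood F. Those of list medians came from resampling the list's genes, so they measure spread between genes, not between libraries. CPM values are TMM-normalized. Pairs of libraries within a group differed beyond counting noise, with chi-square per degree of freedom from 3.71 to 34.6, so none was counted as a copy. Depth ranged from 15292736 to 17923656 counts, and groups of 3 cannot give an exact permutation p under 0.1 for a single value per library.

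Before the data were examined, 37 gene lists were fixed, of which 33 had at least 4 genes tested. Each was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry were alternatives. Calls lost with an estimated correlation need not be due to that correlation alone. For chondrocyte markers at 72 h against 24 h it was 0.0087, under the preset, yet the camera p went from 0.0155 to 0.0514. Genes were named by a rule also fixed then. It took the 8 largest increases and 8 largest decreases (5 and 5 for 72 h against 24 h) among genes with adjusted p under 0.05, mean CPM of at least 5 and no overlap between groups, skipping predicted gene symbols. It added the 4 members with the smallest p of each list described (6 for complex I subunits and ATF4 targets) and a fixed set of genes of complex I and flavin supply. Some members named by this rule are not reported here. Macrophage, endothelial, adipocyte and skeletal muscle markers had too few genes tested for camera.

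The fit was tested on simulated counts with the means and depths of these libraries and 200 genes changed at 24 h, in a step of 13819 genes. The 200 came from genes with a mean above 1 CPM, and a further list of genes was shifted by 0.3 on the log2 scale. The fit recovered 52.2% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 87.9% of those changed 4-fold, and 3.21% of its calls were unchanged genes. Camera with the preset correlation called the shifted list and also 1 of 33 other lists. Genes were drawn independently, so this does not show how often camera calls unchanged lists whose genes vary together. For complex I subunits at 24 h the estimated correlation in the real data was 0.66. Alternatives were other scalings, filters and tools (DESeq2 1.42.0, limma voom), fitting only the groups compared, a replicate block, each library left out and stricter thresholds. The planned limma fit on the second table was run on its counts with voom, since they were not normalized. A fit with unrounded counts was not run, because the counts were whole as deposited. A correction for exonic length and GC content, by a loess of each library's log2 ratio to the mean library, was chosen after seeing the data, as was edgeR on the genes of the second table.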

Results

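RNA was sequenced from mouse adult fibroblasts in 9 libraries. Of these, 3 were from controls, 3 from cells exposed to DPI for 24 h and 3 from cells exposed for 72 h. The treatment label of the controls does not say whether they were untreated or given a vehicle. DPI is taken here as diphenyleneiodonium, an inhibitor of flavoenzymes, from the series' theme of flavin cofactor targeting. The labels gave neither its dose nor the time at which the controls were collected. Time in culture therefore cannot be told apart from DPI for any gene or list below, also at 72 h against 24 h. Total counts per library ranged from 15292736 (control 3) to 17923656 (control 2), and 14088 genes were tested. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Control replicate 2 stood apart from the other controls. Its score on the second principal component was 44.2, against 14.1 and 18.0 in controls 1 and 3, and ribosomal protein genes took 4.87% of its counts, against 3.60% and 3.64%.

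The 24 h comparison asked which transcripts differed after the shorter exposure to DPI. Sterol synthesis genes rose together and targets of ATF4, the transcription factor of the integrated stress response, fell together. Of 23 measured genes for sterol synthesis and the LDL receptor, 22 rose and 0 fell, with a median log2 fold change of 1.25 (camera adjusted p = 3.89e-30). Hmgcs1, which makes the precursor of mevalonate, went from 166 to 439 CPM, a log2 change of 1.40 ± 0.05 (SE, edgeR adjusted p = 6.94e-08). Of 30 ATF4 and stress response genes, 25 fell and 1 rose, with a median of -0.78 (camera adjusted p = 1.08e-17). Cth, an enzyme of cysteine synthesis on chromosome 3 from 157894248 to 157925077 (GRCm38), went from 86.4 ± 4.64 to 10.6 ± 0.308 CPM (SD, n = 3), a log2 change of -3.02 ± 0.08 (SE, edgeR adjusted p = 3.39e-09). Adjusted over the list alone, 22 sterol genes rose and 26 stress response genes fell.

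Other members of the stress response list moved the same way. Vldlr changed by -2.69, Trib3 by -1.80, Ero1l by -1.66, Asns, the asparagine synthetase, by -1.25 and Slc6a9 by -0.95 on the log2 scale. In the list of serine, glycine, one-carbon and proline synthesis, 9 of 16 genes fell and 1 rose, with a median of -0.52 (camera adjusted p = 8.53e-06). Aldh1l2 changed by -2.11, Pycr1 by -2.06, Psph by -1.30 and Mthfd2 by -0.91. Adjusted over the list alone, 9 of these genes fell and 2 rose. The sterol genes Acat2, Lss and Insig1 rose by 1.71, 1.56 and 1.35. These calls held with an estimated correlation between genes, at adjusted p = 0.0027 for sterol genes, 0.011 for stress response genes and 0.040 for serine and one-carbon genes.

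Matrix genes and the list of metalloproteinases, cytokines and chemokines rose at 24 h, and interferon-stimulated genes fell. Of 22 collagen and matrix genes, 19 rose and 0 fell, also when adjusted over the list alone, with a median of 0.73 (camera adjusted p = 2.36e-13). This call was lost at adjusted p = 0.149 with an estimated correlation. Col1a1, a chain of type I collagen, went from 1705 to 4169 CPM, a log2 change of 1.29 ± 0.09 (SE), and Tnc, Loxl2 and Col1a2 rose by 1.70, 1.29 and 0.77. Control replicate 2 had the lowest score for this list, -0.71 against -0.24 and -0.41 in the other controls. The list of metalloproteinases, cytokines and chemokines held 25 genes, of which 13 were tested, with Mmp2 the only metalloproteinase among them. Of these 13, 9 rose and 0 fell, also when adjusted over the list alone, with a median of 0.70 (camera adjusted p = 8.83e-07). This held at adjusted p = 0.016 with an estimated correlation. The chemokine gene Cxcl12 rose by 2.41, Lif by 0.95, Mmp2 by 0.82 and Vcam1 by 0.81. Of 29 interferon-stimulated genes, 22 fell and 2 rose, with a median of -0.90 (camera adjusted p = 2.36e-13), and 23 fell when adjusted over the list alone. This call was lost at adjusted p = 0.149 with an estimated correlation. Ifi44 changed by -3.01, Irf7 by -1.87 and Bst2 by -1.53.

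Nuclear subunit genes of complex I changed little at 24 h. Of 19 assembly factor genes tested, 1 fell and 0 rose. Of 13 mitochondrial DNA mRNAs, which include complex I subunits, 1 rose and 2 fell, and the rise lost its call with some libraries left out. Neither of these 2 lists passed (camera adjusted p = 0.21 and 0.97). Of 36 nuclear subunit genes, 5 fell and 0 rose, 4 when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.0013). The call was lost at adjusted p = 0.70 with an estimated correlation. Without control replicate 2 the median was -0.04 and the camera adjusted p was 0.30. The list score of that library was 0.36, against -0.04 and -0.03 in the other controls. The 5 that fell were Ndufb9 (-0.42), Ndufa7 (-0.46), Ndufa6 (-0.48), Ndufc2 (-0.48) and Ndufb5 (-0.26), and of these Ndufb9 passed with each library left out in turn. Ndufa7 had adjusted p = 0.058 without DPI 24 h replicate 1 and Ndufa6 0.060 without DPI 24 h replicate 2. Ndufc2 had adjusted p = 0.078 and 0.094 without DPI 24 h replicates 2 and 3. Ndufb5 lost its call without any of control replicates 2 and 3, the 3 DPI 24 h replicates and the 3 DPI 72 h replicates, at adjusted p from 0.052 to 0.115. Ndufv1, the subunit that binds FMN, had 117 ± 19.3 CPM in controls and 112 ± 2.03 CPM at 24 h (SD, n = 3), a log2 change of -0.06 ± 0.11 (SE, edgeR adjusted p = 0.75). Ndufv2, Ndufs1, Ndufs4, Ndufa9 and Ndufb8 had log2 changes of -0.24, -0.08, -0.18, -0.09 and -0.16, and none passed. Rfk, which makes FMN from riboflavin, fell by 0.31 on the log2 scale (SE 0.08, edgeR adjusted p = 0.015), with adjusted p = 0.068 when DPI 24 h replicate 3 was left out. Flad1, Slc52a2, Slc25a32 and mt-Nd1 had log2 changes of -0.24, -0.09, 0.19 and 0.19, and none passed. Ndufv2 passed without control replicate 1 (adjusted p = 0.043), with no filter on low counts (0.030) and after a length and GC correction chosen after seeing the data (0.042). In the same way mt-Nd1 passed without control replicate 1 (0.044) and after the correction (0.016), and Slc25a32 without control replicate 2 (0.025). Ndufs7 had a log2 change of -0.41 and did not pass (adjusted p = 0.051), but passed in 7 other settings, at 3.13e-04 to 0.048, among them without control replicate 1 (0.045) and without control replicate 3 (0.014).

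Across all genes, 3478 changed at 24 h, 1750 higher and 1728 lower, at an edgeR adjusted p under 0.05. The largest increases by the naming rule were in Sprr1a, a cornified envelope gene (log2 change 3.10), Angptl4 (2.80), Esm1 (2.49), Dapk2 (2.47), Macc1 (2.39), Camk2b (2.38) and Itgb2 (2.28), besides Cxcl12. The largest decreases were in Avil (-5.49), Car6 (-5.13), Cdsn (-4.62), Angptl6 (-3.49), Ptx3 (-3.37) and Ugt1a6a (-2.87), besides Cth and Ifi44. In all, 20 of 33 lists passed, 8 upward and 12 downward, and 4 of them held with an estimated correlation. Among the other lists that rose were fatty acid and triglyceride synthesis (median 0.44), G1/S genes (0.10), G2/M genes (0.13), chondrocyte markers (0.56) and myofibroblast genes (0.16). Their adjusted p with an estimated correlation was 0.149, 0.31, 0.24, 0.149 and 0.24. The list called myofibroblast genes here also holds targets of SRF and YAP, and of 14 genes tested 5 rose and 1 fell. Its member Acta2, named after its values were seen, had 9.92 to 12.8 CPM at 24 h, against 17.5 to 22.8 in controls. Among the others that fell were cytosolic aminoacyl-tRNA synthetases (-0.37), mitochondrial chaperones and proteases (-0.22), NRF2 targets (-0.20), HIF1 targets (-0.15), p53 targets (-0.12), aryl hydrocarbon receptor targets (-0.24), complexes II to V (-0.13) and mitochondrial ribosomal proteins (-0.10). Their adjusted p with an estimated correlation was 0.149, 0.149, 0.36, 0.20, 0.149, 0.20, 0.78 and 0.78. Without control replicate 2 the medians of complexes II to V and of mitochondrial ribosomal proteins were 0.04 and 0.02, at camera adjusted p = 0.64 and 0.84. Complexes II to V had camera adjusted p = 0.057 without DPI 24 h replicate 2, and aryl hydrocarbon receptor targets 0.055 without control replicate 1. Myofibroblast genes had 0.055, 0.050, 0.055 and 0.059 without control replicates 1 and 3 and DPI 24 h replicates 1 and 2. With a correction for exonic length and GC content, chosen after seeing the data, complexes II to V, mitochondrial ribosomal proteins and myofibroblast genes lost their calls, at adjusted p = 0.38, 0.43 and 0.065.

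The 72 h comparison asked the same of the longer exposure. Interferon-stimulated genes were far lower than in controls, and genes of the hypoxia response and glycolysis were higher. Of 29 interferon-stimulated genes, 28 fell and 0 rose, also when adjusted over the list alone, with a median log2 fold change of -2.85 (camera adjusted p = 2.56e-43, and 0.020 with an estimated correlation). Irf7, a transcription factor of the interferon response on chromosome 7 from 141262706 to 141266481 (GRCm38), went from 43.5 ± 6.75 to 2.31 ± 0.258 CPM (SD, n = 3), a log2 change of -4.23 ± 0.17 (SE, edgeR adjusted p = 2.08e-07). Isg15 changed by -2.99, Bst2 by -2.88 and Oasl1 by -2.29. Usp18 (-4.27), Ifi44 (-3.99), Xaf1 (-3.58), Oasl2 (-3.54), Ifit3 (-3.38), Phf11d (-3.24) and Cmpk2 (-3.17) made up, with Irf7, the 8 largest decreases.

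Of 19 HIF1 targets outside glycolysis, 15 rose and 0 fell, 16 when adjusted over the list alone, with a median of 0.57 (camera adjusted p = 2.07e-22, and 0.0040 with an estimated correlation). Car9, a carbonic anhydrase, went from 8.19 ± 1.10 to 50.6 ± 2.97 CPM (SD, n = 3), a log2 change of 2.63 ± 0.14 (SE). Pdk1, P4ha2 and Egln1 rose by 1.25, 0.89 and 0.79. Of 21 genes of glycolysis and lactate export, 15 rose and 0 fell, with a median of 0.56 (camera adjusted p = 1.32e-14). This call was lost at adjusted p = 0.079 with an estimated correlation. Adjusted over the list alone, 15 rose and 1 fell. Ldha, lactate dehydrogenase, rose by 0.82, Pfkl by 0.74, the glucose transporter gene Slc2a1 by 0.71 and Pkm by 0.58.

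Lysosomal genes fell at 72 h, and sterol and matrix genes were still above control. Of 29 lysosome and autophagy genes, 19 fell and 0 rose, 24 when adjusted over the list alone, with a median of -0.41 (camera adjusted p = 3.05e-20, and 0.036 with an estimated correlation). Gpnmb changed by -2.57, Gla by -0.85, Sqstm1 by -0.79 and Ctsa by -0.71. Of 23 sterol genes, 19 rose and 0 fell, 21 when adjusted over the list alone, with a median of 0.51 (camera adjusted p = 1.00e-22, and 0.0040 with an estimated correlation). Hmgcs1, Acat2 and Sqle rose by 0.70, 0.61 and 0.55. Of 22 collagen and matrix genes, 13 rose and 0 fell, 14 when adjusted over the list alone, with a median of 0.56 (camera adjusted p = 2.28e-14). This call was lost at adjusted p = 0.137 with an estimated correlation. Col6a3, Col1a1, Fbln2 and Col1a2 rose by 1.66, 1.04, 0.68 and 0.65.

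No complex I nuclear subunit gene passed at 72 h, 0 of 36 by edgeR over all genes and 0 over the list alone. The list median was -0.11 (camera adjusted p = 0.022, and 0.73 with an estimated correlation). Without control replicate 2 it was 0.02, at camera adjusted p = 0.36, and without DPI 72 h replicate 1 the adjusted p was 0.072. With a correction for exonic length and GC content, chosen after seeing the data, the median was -0.04 and the adjusted p 0.35. Among the genes named by the rule, Ndufv3 passed upward without control replicate 2 (0.35, adjusted p = 0.028) and after that correction (0.31, adjusted p = 0.031), and Ndufc2 downward with no filter on low counts (-0.34, adjusted p = 0.0094). Ndufv1 had 107 ± 10.2 CPM (SD, n = 3), a log2 change from control of -0.12 ± 0.11 (SE, edgeR adjusted p = 0.57). Ndufv2, Ndufs1, Ndufs4, Ndufa9, Ndufb8, mt-Nd1, Rfk, Flad1, Slc52a2 and Slc25a32 had log2 changes of -0.04, 0.02, -0.16, -0.06, -0.01, 0.13, -0.15, -0.29, -0.06 and 0.13, and none passed. Of 19 assembly factor genes tested, 1 rose and 1 fell (camera adjusted p = 0.18). Of 13 mitochondrial DNA mRNAs, which include complex I subunits, 0 rose and 2 fell (camera adjusted p = 0.043). Each of these gene calls was lost with some libraries left out. ATF4 and stress response genes had a median of 0.02, with 8 of 30 higher and 2 lower, and the list did not pass (camera adjusted p = 0.10). It passed upward without control replicate 2 (median 0.12, adjusted p = 8.03e-04), without DPI 72 h replicate 2 (0.06, adjusted p = 0.032) and after the length and GC correction (0.05, adjusted p = 0.022).

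Across all genes, 1206 changed at 72 h, 666 higher and 540 lower. The balance turned among those with a log2 change of at least 1, with 84 higher and 141 lower. The largest increases by the naming rule, besides Car9, Col6a3 and Sprr1a (1.64), were in Apln (1.94), Rgs2 (1.63), Aqp1 (1.45), Egln3 (1.37) and Lbh (1.35). The count was 1965 without control replicate 2, and 782, 736 and 801 without DPI 72 h replicates 1, 2 and 3. It was 774 when only the 6 libraries compared were fitted. In all, 15 lists passed, 7 upward and 8 downward, and 4 of them held with an estimated correlation. The others that rose were fatty acid and triglyceride synthesis (median 0.39), epithelial markers (0.44) and chondrocyte markers (0.08), at adjusted p = 0.079, 0.17 and 0.20 with an estimated correlation. The others that fell were NRF2 targets (-0.17), p53 targets (-0.13), mitochondrial DNA mRNAs (-0.22), complexes II to V (-0.10) and mitochondrial ribosomal proteins (-0.11). Their adjusted p with an estimated correlation was 0.25, 0.137, 0.57, 0.75 and 0.67. Without control replicate 2 the medians of complexes II to V and of mitochondrial ribosomal proteins were 0.05 and 0.0038, at camera adjusted p = 0.056 and 0.81. Mitochondrial DNA mRNAs had camera adjusted p = 0.29 without control replicate 1 and 0.28 without DPI 72 h replicate 1. Complexes II to V had 0.052, 0.053 and 0.15 without DPI 24 h replicates 2 and 3 and DPI 72 h replicate 1. Epithelial markers had 0.065 and 0.089 without control replicates 1 and 3, and chondrocyte markers 0.17 and 0.056 without control replicate 2 and DPI 72 h replicate 1. After the length and GC correction, the calls of mitochondrial DNA mRNAs, complexes II to V, mitochondrial ribosomal proteins and chondrocyte markers were lost, at adjusted p = 0.56, 0.64, 0.11 and 0.107.

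**Figure D1:**
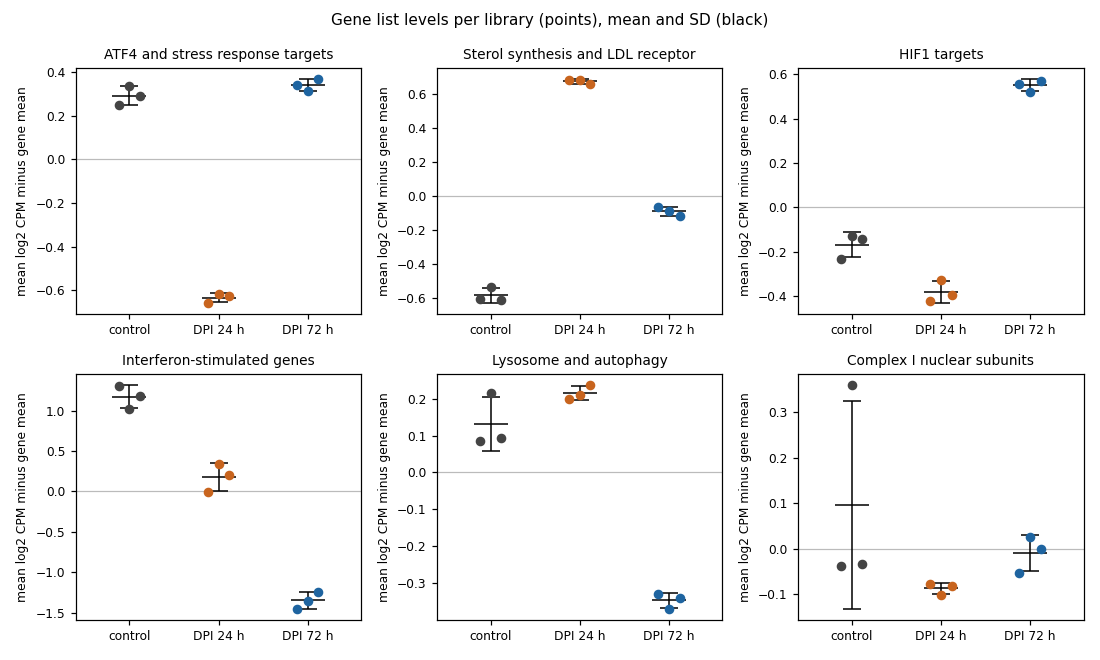
Each point is 1 library, and its height is the mean over a list's genes of log2 CPM minus the gene's mean over all 9 libraries. Black marks are the group mean and SD (n = 3). The ATF4 list was low in the 24 h libraries alone, and for complex I subunits control replicate 2, at 0.36, lay above all 8 other libraries.

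The direct comparison of 72 h with 24 h asked which effects differed between the exposures. It compared the treated libraries with each other, while the controls entered the shared estimate of the spread. ATF4 targets were higher at 72 h than at 24 h in 24 of 30 genes and lower in 1, with a median log2 difference of 0.87 (camera adjusted p = 1.27e-18, and 0.0050 with an estimated correlation). HIF1 targets were higher in 16 of 19 and lower in 2, with a median of 0.99 (camera adjusted p = 1.06e-15, and 0.0050 with an estimated correlation). Sterol genes were lower in 22 of 23, with a median of -0.73 (camera adjusted p = 9.75e-24, and 0.0050 with an estimated correlation). Interferon-stimulated genes were lower in 27 of 29, with a median of -1.59 (camera adjusted p = 1.27e-18). With an estimated correlation this last call was lost at adjusted p = 0.065. Adjusted over each list alone, 24 ATF4 targets and 16 HIF1 targets were higher, and 22 sterol and 28 interferon-stimulated genes were lower.

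Cdsn, Car6, Vldlr, Rgs2 and Cth were the genes most increased from 24 h to 72 h by the naming rule, with log2 differences of 4.02, 3.62, 3.48, 3.43 and 2.79. The most decreased were Gvin1 (-4.04), a gene of a family of near-identical copies whose reads may be shared, Itgb2 (-3.25), Gpnmb (-3.15), Macc1 (-2.71) and Il1rn (-2.58). Lysosome and autophagy genes were lower in 22 of 29 (median -0.54, adjusted p = 0.046 with an estimated correlation), and metalloproteinase, cytokine and chemokine genes in 10 of 13 (median -0.96, adjusted p = 0.0050 with an estimated correlation). No complex I nuclear subunit gene passed by edgeR, 0 of 36, with a list median of 0.08 (camera adjusted p = 0.14, and 0.032 without control replicate 2). This count rested on control replicate 2. Among the subunit genes named by the rule, Ndufa7, Ndufv2, Ndufb11, Ndufb9, Ndufb5, Ndufb8 and Ndufv3 passed upward without that library, by 0.14 to 0.30 on the log2 scale (adjusted p from 8.62e-04 to 0.048), as they did with only the 6 libraries compared (0.0013 to 0.034). All of these except Ndufb5 and Ndufb8 also passed after the length and GC correction (0.0061 to 0.049). Rfk, not called, passed upward in the same 3 settings, at 0.043, 0.041 and 0.04997. Across all genes, 3001 differed, 1427 higher and 1574 lower at 72 h. The count was 4729 without control replicate 2, whose spread entered the shared estimate, 1953 without DPI 24 h replicate 3, and 4660 when only the 6 libraries compared were fitted.

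**Figure D2:**
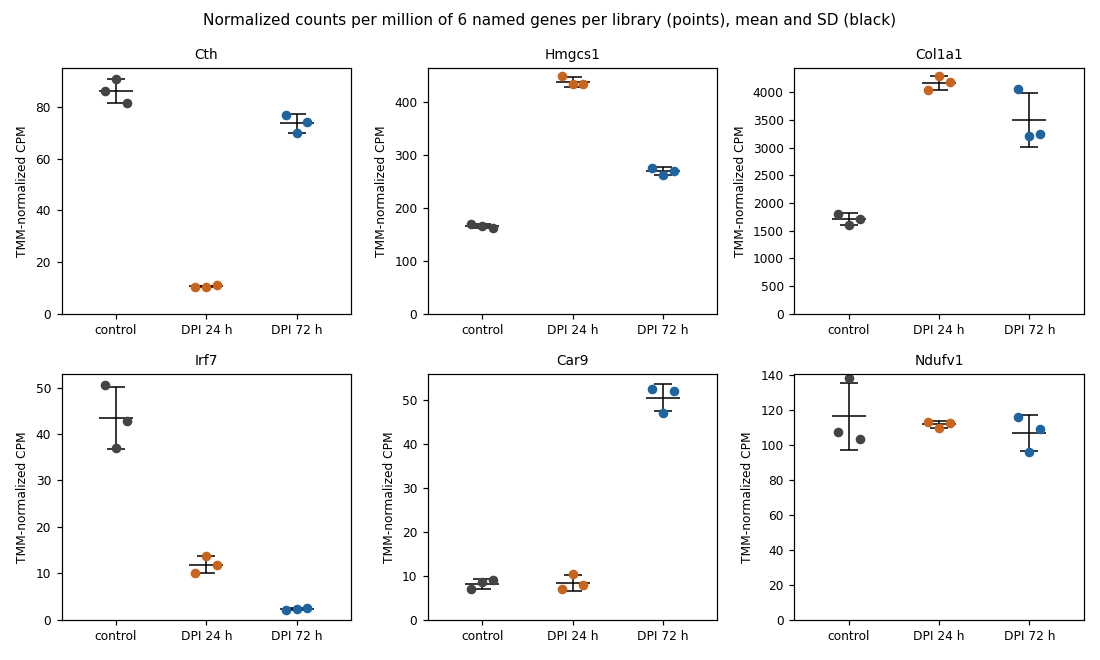
Each point is the TMM-normalized CPM of 1 library, on an axis starting at 0, with the group mean and SD (n = 3) in black. Cth was near 10.6 CPM at 24 h and 73.7 CPM at 72 h, Car9 rose to 50.6 CPM at 72 h, and the 3 groups overlapped for Ndufv1.

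Any change among the 3 groups was found in 4011 genes by the edgeR F-test. Against control, 616 genes differed in the same direction at both exposures, 405 higher and 211 lower, and 133 genes in opposite directions. The 616 became 1037 without control replicate 2 and 390 without DPI 72 h replicate 2. Unchanged groups simulated against the same controls shared 0.02 genes on average over 50 draws. Almost no gene is called where none changed, so that value is no reference for lists of these sizes. Independent lists of these sizes would share 82.7 higher and 66.2 lower genes. The 3 controls cannot be divided into 2 sets of at least 2 libraries, so part of the overlap may come from the shared controls. Across genes, which are not independent replicates, the log2 changes at 24 h and 72 h correlated at 0.40, against 0.51 in the simulations. Their covariance was 0.114, against 0.059 in the simulations. Use of the same controls for both changes sets the simulated correlation of 0.51 in advance. The 0.40 beside it therefore does not show how far the exposures agree.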

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

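The tests of single control libraries, time in culture, leukocyte RNA, and length and GC bias in the complex I list were chosen after the results were seen, as was the length and GC correction itself. Effects of the 24 h and 72 h exposures were compared by testing 72 h against 24 h directly, with edgeR for genes and camera for lists, both at adjusted p under 0.05. Of 33 lists, 14 differed, and of 86 genes reported for either exposure, 63 differed. Most of these genes were picked by their change in the same treated libraries, so a high share follows partly from that choice. Over all genes tested, 3001 of 14088 differed (21.3%).

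Lists higher at 72 h than at 24 h, by median log2 difference, were epithelial markers (1.21), HIF1 targets (0.99), ATF4 targets (0.87), aryl hydrocarbon receptor targets (0.74), serine, glycine, one-carbon and proline synthesis (0.67), glycolysis (0.61), cytosolic aminoacyl-tRNA synthetases (0.46) and mitochondrial chaperones and proteases (0.22). With an estimated correlation, adjusted p was 0.0050 for HIF1 targets and ATF4 targets and 0.018 for serine and one-carbon genes. It was 0.108, 0.146, 0.089, 0.108 and 0.131 for epithelial, aryl hydrocarbon receptor, glycolysis, synthetase and chaperone genes, whose calls were lost. The epithelial median rested on 6 of 15 markers, of which 3 were higher and 0 lower. Over all libraries its member Krt14 averaged 0.77 CPM and Krt19 24.8 CPM. Lists lower at 72 h were interferon-stimulated genes (-1.59), metalloproteinases, cytokines and chemokines (-0.96), sterol synthesis (-0.73), lysosome and autophagy (-0.54), chondrocyte markers (-0.48) and G2/M genes (-0.16). With an estimated correlation, adjusted p was 0.0050 for the list of metalloproteinases, cytokines and chemokines and for sterol genes, and 0.046 for lysosomal genes. Calls were lost for interferon, chondrocyte and G2/M genes, at 0.065, 0.131 and 0.089.

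Among the genes reported above for 24 h or 72 h, those of amino acid metabolism and the stress response were higher at 72 h than at 24 h, by log2 differences of 3.48 (Vldlr), 2.79 (Cth), 2.07 (Ero1l), 2.05 (Aldh1l2), 1.79 (Pycr1), 1.76 (Trib3), 1.27 (Asns), 1.21 (Psph), 0.99 (Slc6a9) and 0.96 (Mthfd2). Hypoxia and glycolysis genes were higher by 2.58 (Car9), 1.77 (Pdk1), 1.63 (Egln3), 1.25 (Slc2a1), 1.16 (P4ha2), 1.15 (Pfkl), 0.89 (Ldha), 0.82 (Egln1) and 0.30 (Pkm). Other members of these lists were lower, 2 of the HIF1 list and 1 of the glycolysis list. The matrix genes Col6a3 and Fbln2 were higher by 0.74 and 0.30. Other genes were higher by 4.02 (Cdsn), 3.62 (Car6), 3.43 (Rgs2), 2.73 (Ptx3), 2.602 (Ugt1a6a), 2.56 (Avil), 2.34 (Angptl6), 0.82 (Lbh) and 0.75 (Aqp1).

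Interferon-stimulated genes were lower at 72 h than at 24 h, with log2 differences of -2.56 (Usp18), -2.45 (Ifit3), -2.40 (Cmpk2), -2.36 (Irf7), -1.91 (Xaf1), -1.89 (Isg15), -1.84 (Oasl2), -1.61 (Phf11d), -1.53 (Oasl1), -1.35 (Bst2) and -0.98 (Ifi44). Sterol genes had -1.10 (Acat2), -1.05 (Lss), -0.84 (Insig1), -0.70 (Hmgcs1) and -0.64 (Sqle). Matrix and lysosomal genes and those of the metalloproteinase, cytokine and chemokine list had -3.15 (Gpnmb), -2.003 (Cxcl12), -1.21 (Mmp2), -1.19 (Gla) and -0.96 (Vcam1). Further genes of these lists had -0.95 (Ctsa), -0.81 (Lif), -0.56 (Tnc), -0.52 (Loxl2) and -0.31 (Sqstm1). Of 22 collagen and matrix genes, 3 were higher and 6 lower, and the list did not pass (camera adjusted p = 0.072). It passed downward without control replicates 1 and 2, DPI 24 h replicate 1 and DPI 72 h replicate 1, at 0.018 to 0.043. Other genes had -3.25 (Itgb2), -2.71 (Macc1), -2.35 (Dapk2), -1.998 (Camk2b), -1.47 (Esm1), -1.46 (Angptl4) and -1.45 (Sprr1a).

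ATF4 targets were low at 24 h and near control at 72 h. Length and GC bias is argued against as the whole cause, because the 24 h median was -0.81 after correction (SE 0.13), against -0.78 before. The SE of a list median, here and below, is over the list's genes, which are not independent replicates. A single control library is also argued against, since the median nearest 0 with 1 control left out was -0.77. Time in culture stays open, since 0 of 3 controls carry a time label, so it cannot be told apart from DPI. An effect of DPI that passed by 72 h may explain the pattern, as a hypothesis that was not tested. Control libraries of the same times would decide it.

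Interferon-stimulated genes fell at 72 h by a median of 2.85 on the log2 scale. The length and GC correction left -2.78, and the median nearest 0 with 1 control library left out was also -2.78, which argues against either as the whole cause. Leukocyte RNA in the controls is argued against, since leukocyte markers lost 0.156% as much summed CPM as the interferon list, with 8.30 CPM in controls and 6.76 at 72 h, against 1291 and 304 CPM for the list. Time in culture cannot be told apart from DPI, as 0 of 3 controls carry a time label. An effect of DPI may explain the fall, as a hypothesis that was not tested and that control libraries of the same times would decide.

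Complex I subunit genes had a median of -0.18 at 24 h, and this rested on control replicate 2. Without that library the median was -0.045 (SE 0.034, camera adjusted p = 0.30), so 1 control library may be the source. In control 2 the deviation of genes from their mean over all 9 libraries correlated with exonic length at -0.59 (Spearman, across 9655 genes, which are not independent replicates), against 0.08 to 0.22 in the other libraries. After the length and GC correction the median was -0.11 (SE 0.02, camera adjusted p = 0.012), which does not decide whether length or GC bias is the cause at 24 h, while at 72 h the call ended after it (median -0.04, adjusted p = 0.35). A small effect of DPI on these genes stays open.

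For 24 h against control, 1 of the 10 splits of the 6 libraries, the real one, gave 3478 genes, and the highest other gave 1. For 72 h, 1 of 10 gave 1206, and the highest other gave 0. For 72 h against 24 h, 1 of 10 gave 3001, and the highest other gave 1. With 10 splits no share under 0.05 can be reached. For any change among the 3 groups, 1 of 100 splits drawn from 280, the real one, gave 4011 genes and the highest other 1774. This argues against a random division of these libraries as the source. It cannot separate DPI from differences between cultures, since the labels do not say whether a group's libraries came from separate cultures.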

How the results depend on the processing

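Alternatives chosen after seeing the data were the length and GC correction, edgeR on the second table's genes, upper quartile scaling and a 1 CPM filter for the F-test, and all alternatives for the overlap except the threshold of 0.01 and the replicate block. With the adjusted p threshold at 0.01, counts at 24 h, 72 h and 72 h against 24 h were 1904, 627 and 1590, and the overlap 294. With a log2 change of at least 1 they were 499, 225 and 537. With only the libraries compared, 72 h gave 774, 72 h against 24 h 4660 and the overlap 386. The length and GC correction gave an overlap of 943. Over other scalings, filters and tools, counts stayed within 1.5 times those reported. With an estimated correlation, 4, 4 and 6 lists passed, against 20, 15 and 14. With fry, 20, 15 and 20 lists passed. Calls were lost for complex I, complexes II to V and mitochondrial ribosomal proteins at 24 h (adjusted p = 0.21, 0.40 and 0.40) and 72 h (0.48, 0.56 and 0.39), and for mitochondrial DNA mRNAs at 72 h (0.24). Other lists gained a call, among them flavoenzymes inhibited by iodonium compounds, downward at 72 h (0.0010) and between exposures (0.0034). Fry does not compare a list with other genes. With at least 1 CPM in 3 libraries, they were lost for myofibroblast genes (0.055) and aryl hydrocarbon receptor targets (0.0504) at 24 h, complexes II to V at 72 h (0.0503) and aryl hydrocarbon receptor targets between exposures (0.051).

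With 1 library left out, counts ranged from 2351 to 4419 at 24 h, 736 (without DPI 72 h replicate 2) to 1965 (without control replicate 2) at 72 h, and 1953 (without DPI 24 h replicate 3) to 4729 (without control replicate 2) for 72 h against 24 h. At 72 h, 782 and 801 genes passed without DPI 72 h replicates 1 and 3. The F-test ranged from 2695 to 5637, and the overlap from 390 (without DPI 72 h replicate 2) to 1037 (without control replicate 2). Lists past the threshold ranged from 18 to 20, 11 to 17 and 14 to 17. The test direction changed without control replicate 2 for complexes II to V, with medians ranging from -0.20 to 0.037 at 24 h and -0.18 to 0.049 at 72 h. It changed likewise for mitochondrial ribosomal proteins, from -0.17 to 0.021 at 24 h and -0.17 to 0.0038 at 72 h, and for complex I at 72 h, from -0.19 to 0.018. With fry, Schwann and neural markers at 24 h were called upward although their median was -0.45. The cause was not tested. Of 351 calls of genes named by the rule over all lists and comparisons, 50 were lost without DPI 24 h replicate 3, the most for any library. In any setting 0 reversed. Most of these genes were named for their change or small p in the same libraries, so their stability follows partly from that choice.

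Same-numbered libraries did not deviate together (correlations -0.09 to 0.0027), so the numbers were not taken as pairs. With a replicate block, 3000, 911 and 2533 genes passed, the F-test gave 3331 and the overlap 479, and no list call changed. Upper quartile scaling put 40.6% of the 24 h calls higher, against 50.3%. It gave 594 higher and 597 lower genes at 72 h, against 666 and 540, and turned the balance between exposures to 1548 higher and 1399 lower, against 1427 and 1574. In simulated data at 24 h, with the depth, spread and number of these libraries and over 13819 genes, 52.2% of 1.5-fold changes were recovered, and what depth alone limits was not tested. A fit with unrounded counts was not run.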

Other observations

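No explanation was tested in this part. Of 12 chondrocyte markers, 5 were tested, and 2 of these rose at both exposures. The markers not tested averaged from 0 (Matn1) to 0.37 CPM (Matn3) over all libraries, with the cartilage collagen gene Col2a1 at 0.13 CPM. Acan, which encodes the cartilage proteoglycan aggrecan, went from 10.6 ± 2.69 to 48.8 ± 2.29 CPM at 24 h and 24.6 ± 2.84 CPM at 72 h (SD, n = 3), with log2 changes of 2.21 ± 0.15 and 1.22 ± 0.16 (SE). Sox9, a transcription factor of cartilage development, rose by 1.10 at 24 h and 0.55 at 72 h. Sox5, not called at 24 h, passed upward without control replicate 1 (adjusted p = 0.0496) and in 4 other settings, at 0.0015 to 0.046. Of 15 epithelial markers, 6 were tested, of which 2 fell at 24 h and 2 rose at 72 h. Krt14, at under 1 CPM on average in controls, was 1 of those that fell, and lost its call without DPI 24 h replicate 2 (adjusted p = 0.052) and with limma on the second table's genes (0.056). At 72 h it was not called, but passed upward without control replicate 1 (0.020) and in 6 other settings, at 0.019 to 0.047. Krt19 changed by -0.88 at 24 h and 0.89 at 72 h. Of 12 Schwann and neural markers, 5 were tested, of which 1 rose and 2 fell at 24 h, and 2 rose at 72 h. Erbb3, 1 of those that fell, lost its call without control replicates 1 and 3 and DPI 24 h replicates 2 and 3, at adjusted p from 0.081 to 0.102, and Ngfr passed upward at 24 h without DPI 72 h replicate 1 (0.048) and with only the libraries compared (0.040). Sox5, Krt14, Erbb3 and Ngfr were named after their values were seen. Tubb3 changed by -0.45 at 24 h and 0.64 at 72 h, and Nes by 0.78 and 0.43.

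Lists with fewer than 4 genes measured gave counts only. Of 2 macrophage and leukocyte markers, 0 changed at 24 h and 1 fell at 72 h. Of 3 endothelial markers, 1 rose and 1 fell at 24 h and 0 changed at 72 h. Of 3 adipocyte markers, 0 changed at 24 h and 1 rose at 72 h. The calls of these 4 genes (Cd68, Kdr, Egfl7 and Pparg, named after their values were seen) depended on single libraries. Cd68 at 72 h lost its call without any 1 of the 9 libraries, at adjusted p from 0.056 to 0.128. Kdr at 24 h lost it without any 1 of the control or DPI 24 h libraries, at 0.055 to 0.122. Egfl7 at 24 h lost it without control replicates 2 and 3 and DPI 24 h replicates 2 and 3, at 0.066 to 0.114. Pparg at 72 h lost it without control replicates 1 and 3, each DPI 24 h replicate and DPI 72 h replicates 1 and 2, at 0.070 to 0.152. Pparg at 24 h, not called, passed downward without control replicate 3 (0.018), without DPI 72 h replicate 3 (0.041) and in 6 other settings, at 0.012 to 0.049. Kdr at 72 h, not called, passed downward after the length and GC correction (0.048). Erg at 24 h, not called, passed upward without DPI 72 h replicate 2 (0.042) and in 3 other settings, at 0.039 to 0.049. Of 2 skeletal muscle markers, 0 changed at either exposure, but Mylpf at 24 h passed upward without control replicate 1 (0.025) and with limma voom (0.047). Erg and Mylpf were also named after their values were seen. The median and mean of Schwann and neural markers differed in sign at 24 h (-0.45 and 0.10), at 72 h (0.13 and -0.17) and between exposures (0.31 and -0.27), as did those of myofibroblast genes (0.10 and -0.11) and aryl hydrocarbon receptor targets (0.10 and -0.05) at 72 h. Between exposures they also differed for iron and iron-sulfur genes (0.03 and -0.04) and mitochondrial DNA maintenance genes (0.0039 and -0.10). For mitochondrial DNA mRNAs at 24 h, fry gave a downward direction while the median was 0.07.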
